A study of Homo sapiens with 18 samples.

How the data were processed

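Gene expression was measured in MCF-7, an established human breast cancer cell line, with oligonucleotide arrays. The cells carried a Tet-off transgene, which doxycycline in the medium keeps silent and which is switched on when doxycycline is withdrawn. The transgene coded either for LMO4 with a Myc tag or for DN-CLIM, a form of the CLIM (also LDB) cofactors of LIM domain proteins that is described as dominant negative. Groups called low had doxycycline and groups called high did not, for 6 days. The series' design text names 3 distinct cell lines for each protein and states that RNA of 3 experiments was pooled for each cell line. The 3 replicates of a group were therefore read as 3 cell lines and the spread between them as that between cell lines derived from MCF-7. Because doxycycline was withdrawn in every high group and no arrays of cells without a transgene were analysed here, each comparison measured transgene induction and doxycycline withdrawal together.

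Per the labels' protocols, 10 µg of total RNA was made into biotin-labelled cRNA and 15 µg of it was fragmented for hybridization. RNA of the LMO4 cell lines was set on the A and the B array of the HG-U133 set and RNA of the DN-CLIM cell lines on the HG-U133 Plus 2.0 array. The deposited values are a linear hybridization intensity per probe set, and the submitters' processing notes name MAS5, whose version is not given in the sources used here. The 2% trimmed mean of the arrays ran from 500.1 to 500.2, so that a scaling by the authors to 500 was read from the values, none of which were negative. Detection calls were not used here. The number of arrays limits the precision of every value.

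Each of the 3 value tables was analysed on its own because the arrays hold different probe sets and were scaled separately. Values were rescaled within a table to a common 2% trimmed mean, which moved no value visibly, and taken as log2(signal + 16), so that fold changes of dim probe sets are understated. Affymetrix control probe sets were left out of the tests and the upper 60% of the others by mean signal was tested. This left 13329 probe sets of the A array with a mean signal of at least 108, 13546 of the B array with at least 151 and 32768 of the Plus 2.0 array with at least 83.5. High was tested against low with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with an intensity trend, two-sided), adjusted by Benjamini-Hochberg over the probe sets tested in a table, at a threshold of 0.05. Errors of log2 fold changes are the standard errors of this fit, and other errors are SDs over 3 arrays. The LMO4 change minus the DN-CLIM change was tested in the same way over probe sets shared by both tables. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

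Gene symbols came from the platform annotation supplied with the tables. On the A array 19071 probe sets had 1 symbol, 1043 had several and 2169 had none. The corresponding numbers were 15432, 554 and 6659 on the B array and 41097, 1801 and 11777 on the Plus 2.0 array. Symbols were compared with a RefSeq table of assembly GRCh38 and 0 needed updating. Only probe sets with 1 symbol were named. Identifiers that end in x_at mark probe sets whose probes can match transcripts of several genes.

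A total of 14 gene lists with 463 genes were fixed before the data were examined, as were the groups, the tests, the alternatives and the rule for named genes. The lists covered the LIM complex, BMP and TGF-beta signalling, estrogen response, cell cycle, apoptosis regulators, p53 targets, interferon response, integrated stress response, glycolysis and hypoxia, cholesterol synthesis, the mitochondrial ribosome, luminal epithelial markers, basal and mesenchymal markers, and blood and endothelial cell markers. Of the listed genes, 4 were matched through an older symbol and 32 had no probe set with 1 symbol. Each gene was represented by its probe set of highest mean signal, and lists with at least 5 genes tested were tested with limma's camera at a preset correlation between genes of 0.01, adjusted over the lists of a comparison. The rule named, for each comparison, the 10 largest rises and falls that passed and whose high arrays all lay on 1 side of the low arrays, with 1 probe set per gene. Where fewer passed, it added such separated probe sets with an absolute log2 fold change of at least 0.58 in order of p, up to 5 in a direction. For the LMO4 change minus the DN-CLIM change it named the 5 largest differences in each direction that passed and up to 10 genes that passed in both comparisons in the same direction, or had an unadjusted p under 0.01 in both. It also named every probe set of LMO4, LDB1, LDB2, BMP7 and HDAC2, and up to 4 members of smallest p in each list.

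Low and high arrays share replicate numbers in their titles. The numbers were taken to pair the arrays, because the design text has the same cell lines with and without doxycycline and because deviations from the group means correlated within every pair. These correlations were 0.365, 0.311 and 0.593 on the A array, 0.168, 0.146 and 0.302 on the B array and 0.332, 0.303 and 0.249 on the Plus 2.0 array. The fit without the pairing had been fixed in advance as the main one. It ignores the correlation within pairs, which can make its p too large and its counts at a given p lower than chance. Its 0 calls are therefore no evidence that nothing changed. The fit with the cell line as a block (replicate block) is given where it changed a call. It called 14 probe sets in the A array table against 0 without the block.

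The fits were tested on simulated tables with the spreads of the real ones and 200 changed probe sets. Without the block, a log2 change of 1 was recovered in 65% of 100 probe sets in the simulated A array table of 13329 probe sets, 35% in the B array table of 13546 and 12% in the DN-CLIM table of 32768. A log2 change of 2 was recovered in 96%, 88% and 61%. With the block these shares were 96%, 71% and 66% for a change of 1 and 100%, 95% and 86% for a change of 2. False calls numbered 0, 1 and 0 without the block and 12, 10 and 11 with it. Shares and false calls depend on the number and size of the simulated changes. They therefore do not give the power or the error rate in the real tables. In each of these simulated tables, a list shifted by -0.4 on the log2 scale was called and 0 other lists were called by camera, with or without the block. That shift was larger in size than the median of any list called in the main fit of the real tables. The largest of those was -0.39, for interferon response in the DN-CLIM table. Probe sets were simulated independently of each other. These results therefore do not show how camera behaves on real lists whose genes move together.

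Alternatives were the values as deposited, quantile normalization, pseudocounts of 1 and 64, no filter on signal, a filter on the upper 40%, no intensity trend, the replicate block and each array left out in turn. Leaving out 1 array kept the other array of its pair in the fit without the block. Differences between cell lines therefore enter these values. For lists they were also a correlation estimated for each list and the mean over a gene's probe sets. With an estimated correlation, camera calls were also lost where the estimate lay below the preset 0.01. With the block, interferon response on the A array had an estimate of -0.0222 and an adjusted p = 0.393. A call lost in this setting is therefore not by itself evidence that the list's genes moved together. Chosen after the values had been seen were combinations of the block with the other alternatives, each pair left out in turn, exact sign-flip tests over the 6 cell lines of both proteins and a list of metallothionein genes.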

Results

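Expression was profiled on 18 arrays in 6 groups of 3, from MCF-7 breast cancer cells in which withdrawal of doxycycline switched on a transgene for Myc-tagged LMO4 or for DN-CLIM. LMO4 is a LIM-only protein that acts in transcription complexes through the CLIM (LDB) cofactors, and DN-CLIM interferes with those cofactors. The comparisons ask which transcripts differ when either protein is induced, and whether both proteins move the same transcripts. RNA from 3 LMO4 cell lines in the low and the high state was measured on 2 arrays, A and B, with 22283 and 22645 probe sets. RNA from 3 DN-CLIM cell lines was measured on an array with 54675. Median signals of single arrays ranged from 155 to 186 on the A array, from 209 to 226 on the B array and from 117 to 151 on the DN-CLIM arrays. The ratio of 3' to 5' signal of GAPDH and ACTB, a measure of RNA integrity, lay between 0.795 and 1.22 on all 18 arrays.

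The probe sets of the induced protein were examined first. LMO4 probe set 209205_s_at had a signal of 226 ± 32.2 (SD, n = 3) in LMO4 low and 262 ± 18.0 in LMO4 high, a log2 fold change of 0.20 ± 0.18. LMO4 probe set 241922_at had 407 ± 19.5 and 376 ± 42.7. The 3 other LMO4 probe sets, 209204_at, 227155_at and 229537_at, had mean signals of 48.7, 15.8 and 136 in low and 40.8, 11.6 and 117 in high, below the filter. In the DN-CLIM cell lines LMO4 209205_s_at had 449 ± 72.7 in low and 479 ± 68.1 in high. For LDB1, a gene of the CLIM family, probe set 203451_at had 521 ± 52.1 in DN-CLIM low and 651 ± 136 in DN-CLIM high, and 35160_at 561 ± 137 and 539.6 ± 121. LDB2 242360_at had log2 fold changes of 0.16 ± 0.22 with LMO4 and 0.32 ± 0.32 with DN-CLIM, and LDB2 206481_s_at stayed below the filter. No LMO4, LDB1 or LDB2 probe set passed the test in any table. Probe sets can lie in parts of a transcript that the transgenes lack, and where they lie was not determined, so these values do not check the labels.

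With LMO4 induced, the largest log2 fold change among the 10 probe sets named by the rule on the A array was that of PTN, a secreted growth factor, at 309.9 ± 99.9 in low and 725 ± 143 in high (208408_at, 1.21 ± 0.24, log2 fold change with its SE, n = 3 per group). ZFP36L2, an RNA-binding protein that speeds mRNA decay, went from 1097 ± 169 to 1997 ± 122 (201369_s_at, 0.86 ± 0.14), and the metallothionein MT1X from 519 ± 90.4 to 897 ± 14.8 (204326_x_at, 0.79 ± 0.16). The receptor tyrosine kinase RET went from 993 ± 47.7 to 1646 ± 87.6 (205879_x_at, 0.72 ± 0.12) and the acyl-CoA binding protein DBI from 5425 ± 511 to 8520.0 ± 1241 (202428_x_at, 0.64 ± 0.13). Lower in all 3 high arrays than in all 3 low arrays were TBC1D9 (212960_at, -0.75 ± 0.13), WDR48 (221735_at, -0.67 ± 0.15), the orphan receptor GPRC5A (212444_at, -0.59 ± 0.13), coagulation factor XII gene F12 (205774_at, -0.59 ± 0.13) and the LDL receptor's ubiquitin ligase MYLIP (220319_s_at, -0.58 ± 0.13). The MT1X, RET and DBI probe sets are of the x_at kind. None of these 10 passed the threshold: limma called 0 of 13329 probe sets, with 514 at an unadjusted p under 0.05 where chance gives 666. The smallest adjusted p was 0.855.

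With the cell line as a block (replicate block), 14 probe sets passed, 11 of them higher and 3 lower in LMO4 high. At an unadjusted p under 0.05 there were then 1449, 755 higher and 694 lower, against 666 by chance. Higher were ZFP36L2, RET, DBI, MT1X (208581_x_at, 0.79 on the log2 scale), MT1H (0.84), the trefoil peptide TFF3 (0.71), the caveolae protein CAV1 (0.64), CALML5 (1.19), IGFBP5, which binds insulin-like growth factors (0.72), the sodium pump subunit ATP1B1 (0.72) and 212593_s_at, which has several symbols. Lower were both probe sets of TBC1D9 (-0.75 and -0.75) and the interferon-induced ISG15 (-0.62). Their adjusted p lay between 0.0453 and 0.0490, and those outside the rule for named genes were chosen after their values were seen. The block count was 0 without the filter on signal, 0 without the intensity trend, 4 with quantile normalization and 56 with the upper 40% of probe sets. Over the alternatives without the block, single values moved widely: CALML5 from 0.35 to 1.98, IGFBP5 from 0.15 to 1.30, CAV1 from -0.05 to 1.28, TFF3 from 0.35 to 0.99, ATP1B1 from 0.41 to 0.91 and ISG15 from -1.07 to -0.15. These ranges include fits with 1 array of a pair left out, in which differences between cell lines enter. Within cell lines 1, 2 and 3, CALML5 changed by 0.80, 1.47 and 1.32 and IGFBP5 by 0.57, 0.90 and 0.69. CAV1 changed by 0.62, 0.57 and 0.74 and TFF3 by 0.63, 0.61 and 0.90. ATP1B1 changed by 0.67, 0.50 and 1.00 and ISG15 by -0.60, -0.62 and -0.64. Calls with the block favour probe sets with such close values. The block count was 0 without the pair of cell line 1 and 244 without that of cell line 3.

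BMP7, a secreted signal of the BMP family, had higher signal in LMO4 high at 3 of its 4 probe sets. Probe set 209590_at went from 390.5 ± 64.01 to 624 ± 54.4 (SD, n = 3; log2 fold change 0.66 ± 0.16), 209591_s_at from 651 ± 64.4 to 1185 ± 355 (0.81 ± 0.20) and 211259_s_at from 182 ± 38.0 to 401 ± 107 (1.07 ± 0.23). Probe set 211260_at went from 375 ± 121 to 307 ± 36.3 (-0.23 ± 0.24). In DN-CLIM high the log2 fold changes of these probe sets were 0.70 ± 0.39, 0.51 ± 0.23, 0.83 ± 0.27 and 0.40 ± 0.26. Over the alternatives they ran from 0.35 to 1.19, 0.27 to 0.71, 0.61 to 1.02 and 0.19 to 0.62, and 211260_at in the LMO4 cell lines from -0.52 to -0.07. None passed in either table with limma. The smallest adjusted p with the replicate block was 0.0685, at 209591_s_at in the LMO4 cell lines. Over the 6 cell lines of both proteins, 209590_at, 209591_s_at and 211259_s_at were higher in 6 of 6, with mean log2 fold changes of 0.68, 0.66 and 0.95. An exact two-sided sign-flip permutation test gave p = 0.0312 for each, the smallest that 6 pairs allow. This was an adjusted p of 0.0625 over the 8 probe sets of the always-named genes tested in both tables. LMO4 209205_s_at was also higher in 6 of 6, by 0.15 on average, with the same exact p. HDAC2, a histone deacetylase, had a log2 fold change at 201833_at of -0.08 ± 0.24 with LMO4 and -0.07 ± 0.19 with DN-CLIM, and at 242141_at of -0.20 ± 0.25 and 0.36 ± 0.37.

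**Figure D1:**
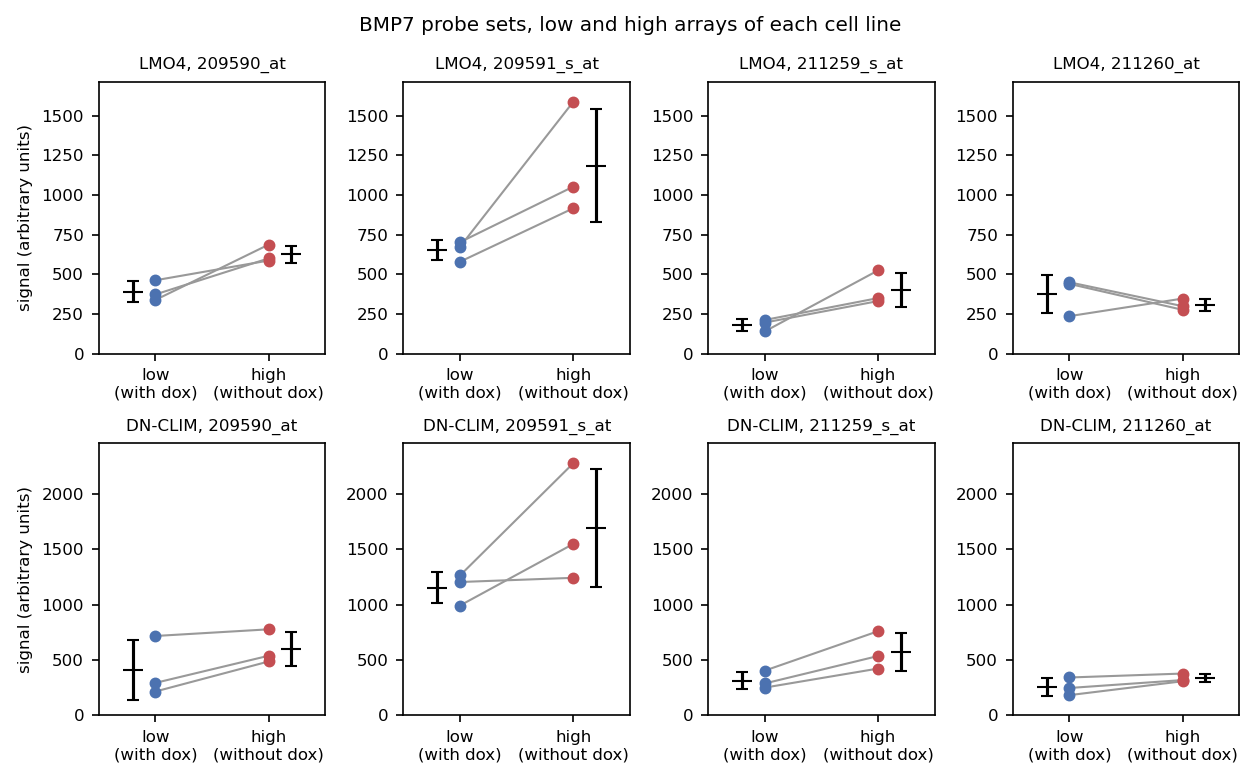
Signal (arbitrary units, vertical axis) of the 4 BMP7 probe sets in the LMO4 cell lines (A array, upper row) and the DN-CLIM cell lines (lower row), in the low state with doxycycline (dox) and the high state without it. Points are single arrays, lines join the arrays of a cell line, and bars give the mean and SD of 3 arrays; 209590_at, 209591_s_at and 211259_s_at were higher in the high state in all 6 cell lines.

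Among the gene lists, interferon response and p53 targets fell in LMO4 high on the A array. Of 31 interferon-response genes tested, 24 had lower and 7 higher mean log2 signal, and the median log2 fold change was -0.25 (camera, adjusted p = 0.00554). The call was lost at an adjusted p = 0.727 with an estimated correlation. Examples were IFIH1, a sensor of double-stranded RNA (-0.61 ± 0.24), ISG20 (-0.47 ± 0.19), the transcription factor IRF9 (-0.51 ± 0.26) and IFITM3 (-0.34 ± 0.14). Of 18 p53 targets, 13 were lower and 5 higher, with a median of -0.18 (adjusted p = 0.0157). This call too was lost, at an adjusted p = 0.416 with an estimated correlation. That estimate was 0.000381, below the preset 0.01, so this loss does not show that the genes moved together. GADD45A, a DNA damage response gene, had -0.77 ± 0.28, DDB2 -0.40 ± 0.20 and the death receptor FAS -0.43 ± 0.25. Adjusted over the list alone, 0 interferon genes and 0 p53 targets passed with limma, and 3 and 1 had an unadjusted p under 0.05. With the replicate block 14 interferon genes passed when adjusted over the list alone, 12 of them lower and 2 higher, and 2 p53 targets, both lower. The 2 higher interferon genes were MX1 (1.10 ± 0.61) and LGALS3BP (0.38 ± 0.20). The interferon call was lost without LMO4 low replicate 3 (adjusted p = 0.789), high replicate 1 (0.346) or high replicate 2 (0.139), with medians of -0.05, -0.15 and -0.17. The p53 call was lost without low replicate 2 (0.171), low replicate 3 (0.0811) or high replicate 3 (0.0579) and with the upper 40% of probe sets (0.254, median -0.09). Over all alternatives the adjusted p ran from 1.83e-09 to 0.789 for interferon response and from 0.00561 to 0.416 for p53 targets, and the median from -0.39 to -0.05 and from -0.18 to -0.09.

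STAT1, a transcription factor of the interferon pathway, is also measured by 4 control probe sets that the tests left out. On the A array the signal of its 3' control probe set was 1959 ± 770.4 in low and 1709 ± 612 in high (SD, n = 3). All 4 were lower in the high array of every cell line on the A and on the B array. In the DN-CLIM table the 3' probe set had 6713 ± 2691 and 4977 ± 1875. It and the MB probe set were lower in 3 of 3 cell lines, the others in 2 of 3.

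The other 12 lists did not pass on the A array. They were apoptosis regulators (12 of 27 genes higher, median -0.01), basal and mesenchymal markers (8 of 13 genes higher, median 0.05), blood and endothelial cell markers (4 of 5 genes higher, median 0.18), BMP and TGF-beta signalling (15 of 29 genes higher, median 0.00), cell cycle (30 of 45 genes higher, median 0.06), cholesterol synthesis (8 of 19 genes higher, median -0.01), estrogen response (17 of 31 genes higher, median 0.06), glycolysis and hypoxia (15 of 26 genes higher, median 0.01), integrated stress response (17 of 30 genes higher, median 0.02), LIM complex (11 of 17 genes higher, median 0.11), luminal epithelial markers (15 of 25 genes higher, median 0.01) and mitochondrial ribosome (14 of 47 genes higher, median -0.04). Without LMO4 high replicate 1, cell cycle passed upward (adjusted p = 0.00669, median 0.12), as did estrogen response (0.0407, median 0.10). Of their members 1 apoptosis regulator passed when adjusted over the list alone, the proapoptotic BIK from 552 ± 55.9 to 919 ± 107 (0.72 ± 0.15, adjusted p = 0.0224), and 1 estrogen-response gene, RET (adjusted p = 0.00547). In the remaining 10 lists limma called 0 members when adjusted over the list alone, and from 0 to 3 per list had an unadjusted p under 0.05. The replicate block, which gave 14 calls over all probe sets, also added members adjusted over the list alone. Estrogen response then had 5, with RET, TFF3 and NRIP1 (0.40) higher and HSPB8 (-0.64) and CA12 (215867_x_at, -0.45) lower. Basal and mesenchymal markers had 4, with CAV1, the cadherin CDH3 (0.40) and the matrix protein FN1 (0.43) higher and the actin ACTA2 (-0.45) lower. Integrated stress response had 3, with DDIT4 (0.52) and ATF5 (0.56) higher and SLC3A2 lower. BMP and TGF-beta signalling had 2 higher, BMP7 (209591_s_at) and LTBP1 (adjusted p = 0.00213 each), luminal markers 2 higher, TFF3 and AGR2, and glycolysis and hypoxia 1 higher, NDRG1. The other 6 of these 12 lists kept their counts. Members of smallest p included TFF3 (0.71 ± 0.33) and AGR2 (0.76 ± 0.33) of the luminal markers, NDRG1 of the hypoxia list (0.66 ± 0.22), the amino acid transporter subunit SLC3A2 (-0.53 ± 0.17), the BMP and TGF-beta list's LTBP1 (0.67 ± 0.28), LHX6 of the LIM complex list (0.52 ± 0.24), AURKA of the cell cycle (-0.31 ± 0.13) and MRPS31 (-0.43 ± 0.13).

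On the B array, LMO4 high had 2482 ± 253 against 1252 ± 129 in low for FRMD8 (227964_at, 0.98 ± 0.14, n = 3 per group). RAD54L2, a helicase-like protein, went from 172 ± 63.1 to 563 ± 75.9 (226624_at, 1.66 ± 0.26). Also higher were SUN5 (237188_x_at, 1.10 ± 0.23), the pseudogene DUXAP10 (242881_x_at, 0.71 ± 0.17) and the lipase LIPH (235871_at, 1.18 ± 0.28). Lower in LMO4 high were NECAB1, a calcium-binding protein, from 1043 ± 109 to 438 ± 114 (233305_at, -1.25 ± 0.20), MMAA of mitochondrial vitamin B12 metabolism (236347_at, -1.64 ± 0.34), the mRNA 3' end processing factor CPSF2 (233208_x_at, -0.76 ± 0.17), FAM167A (226614_s_at, -1.14 ± 0.25) and the GABA receptor subunit GABRB1 (236716_at, -1.49 ± 0.38). None of these 10 passed. Limma called 0 of 13546 probe sets without the block and 0 with it, with 622 and 1186 at an unadjusted p under 0.05 against 677 by chance. SUN5, DUXAP10 and CPSF2 rest on x_at probe sets.

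No list passed on the B array without the block. With the replicate block 2 fell: interferon response (5 of 7 genes lower, median -0.35, adjusted p = 0.0281, against 0.0656 without the block), and mitochondrial ribosome (13 of 18 lower, median -0.13, adjusted p = 0.0489, against 0.0656). Both calls were lost, at an adjusted p = 0.801 with an estimated correlation. Without the block, interferon response passed without LMO4 high B array replicate 3 (adjusted p = 0.000230) and mitochondrial ribosome without low replicate 3 (0.0325) or high replicate 2 (0.0397), and both with the upper 40% of probe sets (0.0298 and 0.0429). Over all alternatives the adjusted p ran from 0.000230 to 0.771 and from 0.0325 to 0.771, and the median from -0.64 to -0.11 and from -0.19 to -0.06. IFIT2 went from 487 ± 214 to 188 ± 128 (-1.40 ± 0.44) and SP110 from 719.6 ± 112 to 541 ± 107; adjusted over the list alone, IFIT2 passed only with the block (adjusted p = 0.00450). Within the mitochondrial ribosome list MRPL37 (-0.26 ± 0.11), MRPS15 (-0.26 ± 0.10) and MRPS22 (-0.28 ± 0.13) lay below 0, while MRPL10 lay above (0.66 ± 0.20) and passed over the list alone only with the block (adjusted p = 0.0114). The other 9 lists tested were apoptosis regulators (5 of 11 genes higher, median -0.02), BMP and TGF-beta signalling (7 of 14 genes higher, median 0.01), cell cycle (7 of 8 genes higher, median 0.19), estrogen response (2 of 5 genes higher, median -0.17), glycolysis and hypoxia (3 of 7 genes higher, median -0.04), integrated stress response (3 of 6 genes higher, median 0.05), LIM complex (5 of 10 genes higher, median 0.00), luminal epithelial markers (4 of 8 genes higher, median 0.08) and p53 targets (3 of 8 genes higher, median -0.11). The camera statistic of apoptosis regulators pointed up although their median was below 0. Without the block limma called 0 members of any of the 11 lists when adjusted over the list alone, and 1 interferon gene, 3 mitochondrial ribosome genes and 1 p53 target had an unadjusted p under 0.05.

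With DN-CLIM induced, the higher probe sets of smallest p named by the rule were those of RALGAPA2, a GTPase-activating protein subunit, from 94.3 ± 36.9 to 489 ± 110.2 (231826_at, 2.23 ± 0.32, n = 3 per group), and PLXNB1, a semaphorin receptor, from 39.2 ± 11.3 to 193 ± 35.1 (215668_s_at, 1.93 ± 0.37). Also higher were MPP3 (206186_at, 0.98 ± 0.21), the small GTPase RAB6B (221792_at, 0.92 ± 0.20) and the noncoding LINC02673 (234506_at, 1.48 ± 0.33). Lower in DN-CLIM high were SEC23B, a coat protein of vesicles leaving the endoplasmic reticulum, from 4636 ± 1152 to 2193 ± 134 (210293_s_at, -1.05 ± 0.19), the membrane protein ITM2B from 3886 ± 1014 to 1993 ± 159.6 (217731_s_at, -0.93 ± 0.19), the small nucleolar RNA SNORA71A (1565858_at, -1.78 ± 0.37), SUCLG2-DT (1557338_x_at, -2.14 ± 0.48) and the phospholipase PLCD3 (234971_x_at, -1.68 ± 0.41), the last 2 on x_at probe sets. None of these 10 passed. Limma called 0 of 32768 probe sets without the block and 0 with it, with 1029 and 2336 at an unadjusted p under 0.05 against 1638 by chance. Of the 1029, 71.3% were higher in DN-CLIM high, 734 against 295 lower. After quantile normalization the set at this p had 438 higher and 414 lower, a share of 51.4%.

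Of the 14 gene lists, 5 fell in DN-CLIM high. In the mitochondrial ribosome list 42 of 53 genes were lower and 11 higher, with a median log2 fold change of -0.18 (camera, adjusted p = 5.59e-08, and adjusted p = 0.265 with an estimated correlation). MRPS11 had -0.41 ± 0.18, MRPL9 -0.38 ± 0.18, MRPL37 -0.32 ± 0.15 and MRPS30 -0.29 ± 0.16. In the interferon list 30 of 34 were lower, with a median of -0.39 (adjusted p = 1.84e-06, and adjusted p = 0.723 with an estimated correlation). The peptide transporter TAP1 had -0.79 ± 0.27, IRF9 -0.52 ± 0.24, IFI6 -0.82 ± 0.52 and ISG15 -0.67 ± 0.45. Of the p53 targets 16 of 20 were lower, median -0.19 (adjusted p = 0.000693, and adjusted p = 0.265 with an estimated correlation), among them FAS (-0.56 ± 0.23), PHLDA3 (-0.22 ± 0.16) and TP53I3 (-0.28 ± 0.20). Of the apoptosis regulators 22 of 30 were lower, median -0.14 (adjusted p = 0.00548, and adjusted p = 0.542 with an estimated correlation), with TRADD at -0.46 ± 0.21 and APAF1 at -0.89 ± 0.41. Of the cholesterol synthesis genes 14 of 20 were lower, median -0.09 (adjusted p = 0.00724, and adjusted p = 0.542 with an estimated correlation), with HMGCS1 at -0.51 ± 0.23, MSMO1 at -0.43 ± 0.19 and IDI1 at -0.39 ± 0.15. Adjusted over the list alone, limma called 0 members of these 5 lists, and 0, 1, 1, 1 and 3 had an unadjusted p under 0.05. The p53 and apoptosis lists both contain FAS, TNFRSF10B, BAX and BBC3, so their falls are not independent. FAS was the member at this p in both. When adjusted over the list alone, 11 interferon genes passed with the replicate block, all lower.

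Several of these calls were lost when 1 array was left out of the fit without the block, while the other array of its pair stayed in. Differences between cell lines enter such a fit. The interferon call was lost without DN-CLIM low replicate 3 (adjusted p = 0.539) or high replicate 1 (0.533). Its median was then -0.06 and -0.02, against -0.39 with all 6 arrays. Within cell lines 1, 2 and 3 the list's mean shift relative to all genes was -0.37, -0.16 and -0.84. The p53 call was lost without low replicate 1 (0.0611). The call of apoptosis regulators was lost without low replicate 1 (0.0680), low replicate 3 (0.0881) or high replicate 2 (0.0834). It was also lost with the mean over a gene's probe sets (0.307). That of cholesterol synthesis was lost without low replicate 1 (0.0690), low replicate 2 (0.0743), high replicate 1 (0.0951) or high replicate 3 (0.144). So it was with quantile normalization (0.0752) and with the mean over a gene's probe sets (0.0733). The mitochondrial ribosome list passed with every single array left out. Over all alternatives the adjusted p ran from 7.56e-10 to 0.265 for the mitochondrial ribosome, 1.12e-18 to 0.723 for interferon response, 3.67e-05 to 0.265 for p53 targets, 0.000300 to 0.542 for apoptosis regulators and 0.000172 to 0.542 for cholesterol synthesis. Their medians ran, in this order, from -0.21 to -0.13, -0.74 to -0.02, -0.23 to -0.11, -0.19 to -0.05 and -0.18 to -0.04. The other 9 lists did not pass. They were basal and mesenchymal markers (13 of 19 genes higher, median 0.11), blood and endothelial cell markers (6 of 8 genes higher, median 0.34), BMP and TGF-beta signalling (15 of 31 genes higher, median -0.00), cell cycle (26 of 46 genes higher, median 0.04), estrogen response (22 of 33 genes higher, median 0.06), glycolysis and hypoxia (12 of 29 genes higher, median -0.02), integrated stress response (21 of 33 genes higher, median 0.06), LIM complex (17 of 26 genes higher, median 0.06) and luminal epithelial markers (11 of 26 genes higher, median -0.03).

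Leaving out 1 DN-CLIM array, with the other array of its pair kept, made 6 of these 9 lists pass. Estrogen response passed upward without low replicate 2 (adjusted p = 0.00111, median 0.24) or high replicate 1 (0.000638, median 0.24). Cell cycle passed upward without low replicate 2 (0.000300, median 0.14) and with quantile normalization (0.0498), and BMP and TGF-beta signalling without low replicate 3 (0.0193, median 0.14). Integrated stress response passed upward without low replicate 3 (0.0336) or high replicate 2 (0.0188, median 0.17). Blood and endothelial markers passed upward without high replicate 3 (0.0283, median 0.48) and with no filter (0.0181). Glycolysis and hypoxia passed upward without high replicate 2 (0.0496, median 0.13) and downward without high replicate 1 (0.00213, median -0.17). Over all alternatives the adjusted p ran from 0.000638 to 0.998 for estrogen response, 0.000300 to 0.952 for cell cycle, 0.0193 to 0.952 for BMP and TGF-beta signalling, 0.0188 to 0.952 for stress response, 0.0181 to 0.748 for blood and endothelial markers and 0.00213 to 0.998 for glycolysis and hypoxia. For the BMP and TGF-beta and the glycolysis lists the camera statistic and the mean pointed up although the median lay below 0, and for luminal markers the mean lay above 0 while median and statistic lay below. Limma called 0 members of these 9 lists when adjusted over the list alone, with 1 cell cycle gene (CDT1, 0.39 ± 0.16), 1 stress response gene (DDIT4, from 1629 ± 223 to 2631 ± 179.8) and 1 LIM complex gene (LMO3, 0.72 ± 0.31) at an unadjusted p under 0.05. With the cell line as a block (replicate block, 0 calls over all probe sets), 1 glycolysis and hypoxia gene passed over the list alone, NDRG1 (adjusted p = 0.0114), and 1 stress response gene, DDIT4 (adjusted p = 0.0336), both higher.

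Over the 3 LMO4 pairs of the A array and the 3 DN-CLIM pairs together, 4 lists were lower in the high state of all 6 cell lines. The mean shift relative to all genes was -0.34 ± 0.26 (SD, n = 6) for interferon response, -0.22 ± 0.05 for p53 targets, -0.13 ± 0.08 for the mitochondrial ribosome and -0.11 ± 0.09 for apoptosis regulators. The p53 and apoptosis lists share genes such as FAS and BAX, so their shifts are not independent. Blood and endothelial markers, most of them dim in these cells, were higher in all 6, at 0.23 ± 0.22. For each of these 5 lists an exact two-sided sign-flip permutation test gave p = 0.0312, the smallest that 6 pairs allow, which adjusted over the 14 lists was 0.0875 and did not pass.

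**Figure D2:**
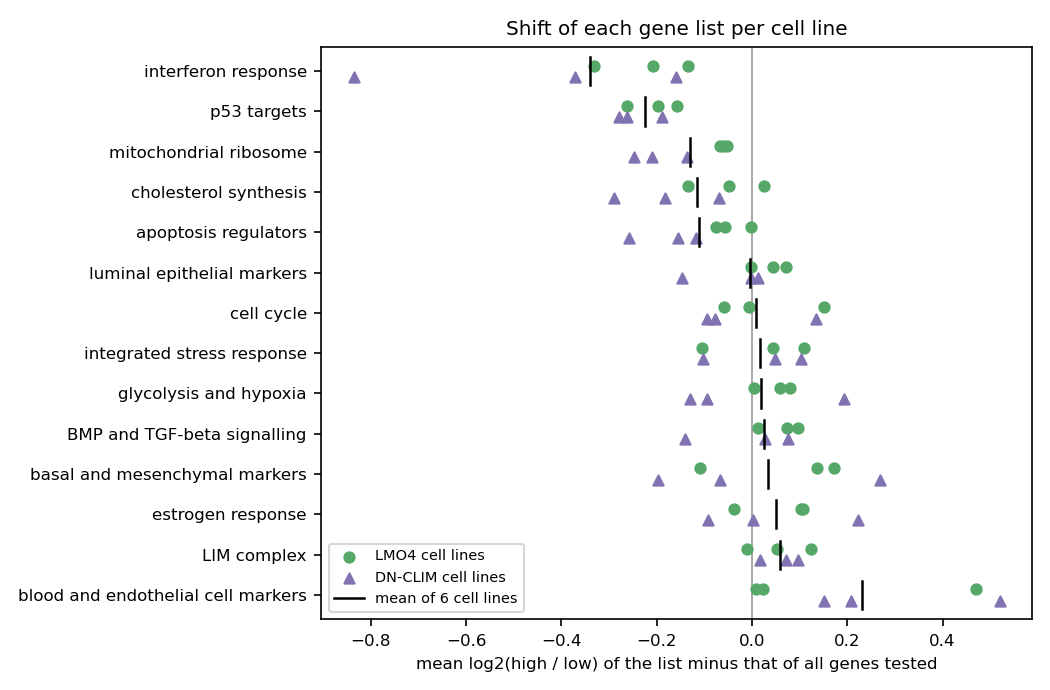
Mean log2 ratio of high over low of the genes of each list minus that of all genes tested (horizontal axis), for 14 gene lists (vertical axis). Circles are the 3 LMO4 cell lines (A array), triangles the 3 DN-CLIM cell lines and vertical bars the mean of 6, and interferon response, p53 targets, mitochondrial ribosome and apoptosis regulators lay below 0 in every cell line.

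The changes with LMO4 and with DN-CLIM were then set against each other. No probe set differed between them past the threshold. Limma called 0 of 13238 shared probe sets of the A array and 0 of 12260 of the B array, with 181 and 343 at an unadjusted p under 0.05 against 662 and 613 by chance. This test ignored the pairing of arrays by cell line, which can make its p too large. Taking the cell line as a replicate block gave 0 and 0 calls, with 585 and 717 at an unadjusted p under 0.05. Across probe sets, which are not independent replicates, the fold changes had a Pearson correlation of 0.278 (Spearman 0.276) on the A array and 0.112 (0.143) on the B array. Both correlations were smaller without the filter on signal, at 0.135 and 0.0507. The A array value was 0.106 without LMO4 low replicate 3 and 0.178 without LMO4 high replicate 1. The B array value was 0.0586 without DN-CLIM low replicate 1 and 0.227 with the upper 40% of probe sets.

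Without the block, 0 probe sets were higher and 0 lower with both proteins at an unadjusted p under 0.01 on either array, so the rule named none. On the B array 2 had opposite signs at that p. With the replicate block, which also gave the 14 calls on the A array, 14 were higher with both and 23 lower with both, against 1.95 and 1.62 for independent lists. These probe sets are not independent of each other: the 34 with 1 symbol cover 29 genes. The excess was not tested. Opposite signs were found for 0. On the B array 2 were higher and 4 lower with both, against 1.22 and 0.365 for independent lists, and 3 had opposite signs. Chosen after these values were seen, the A array genes of smallest p were IGFBP5 (211958_at, log2 fold changes 0.72 with LMO4 and 0.85 with DN-CLIM), NDRG1 (0.66 and 0.74), BMP7 (211259_s_at, 1.07 and 0.83) and the stress-induced DDIT4 (0.52 and 0.69) on the higher side. On the lower side they were F12 (-0.59 and -0.60), the small heat shock protein HSPB8 (-0.64 and -0.90), IRF9 (-0.51 and -0.52), the pregnancy-specific glycoprotein PSG9 (-0.77 and -0.51), the clathrin light chain CLTA (-0.43 and -0.61) and the carbonic anhydrase CA12 (-0.44 and -0.55). PTN had 1.21 and 0.63, and the interferon-induced IFIT1 -1.03 and -1.22.

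**Figure D3:**
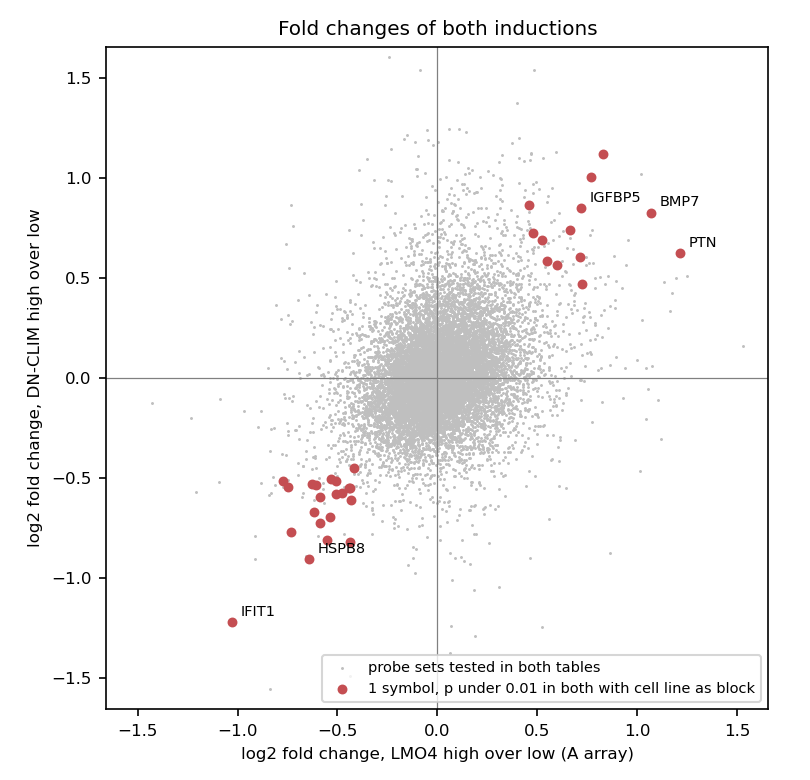
Log2 fold change of high over low with LMO4 (A array, horizontal axis) and with DN-CLIM (vertical axis). Grey points are the 13238 probe sets tested in both tables. Red points are 34 probe sets with 1 symbol, picked for the same sign with both proteins. Their unadjusted p was under 0.01 in both with the cell line as a block, where 0 probe sets had opposite signs.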

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

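The replicate block within splits of the arrays, the list counts of splits that part every pair, the sign-flip tests over 6 cell lines and the values with both arrays of a pair left out were chosen only after the results had been seen. The outcome that each other test below would count for or against an explanation was fixed before that test was run.

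MPP3 (206186_at) and PLCD3 (234971_x_at) had opposite signs with LMO4 and with DN-CLIM, in all 3 cell lines of each. MPP3 had a log2 fold change of -0.23 with LMO4 and 0.98 with DN-CLIM, a difference of -1.22 ± 0.24 (SE). PLCD3 had 0.92 with LMO4 on the B array and -1.68 with DN-CLIM, a difference of 2.60 ± 0.54. Neither difference passed limma's test over all shared probe sets (adjusted p = 1.00 for both). Of the 37 named probe sets measured in both, 13 had 1 sign in all 3 cell lines of each protein, and for 2 of these the signs were opposite.

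Regrouping the 6 arrays of a table gives 10 splits, too few for a share under 0.05. Without the block, the real split called 0 probe sets in each table, as did 10 of 10 splits of the A array. The highest other count was 0 on the A array, 1 on the B array and 0 in the DN-CLIM table. With the replicate block the 14 probe sets of the A array stood against at most 0 in the 3 other splits that part every pair, so that 1 of 4 splits gave as many. All 4 splits gave 0 on the B array and in the DN-CLIM table, and 4 splits are too few as well. For gene lists, 6 of 10 splits gave as many as the 2 of the A array (highest other 3), 10 of 10 as many as the 0 of the B array (highest other 2) and 6 of 10 as many as the 5 of the DN-CLIM table (highest other 8). Among the 4 splits that part every pair the highest other was 3 lists on the A array, 1 on the B array and 4 in the DN-CLIM table. Splits that put both arrays of a cell line on the same side reached 1905 probe sets at an unadjusted p under 0.05 on the A array, against 514 for the real one, and 3095 against 1029 in the DN-CLIM table. Differences between cell lines are therefore part of the structure of these samples. The LMO4 change minus the DN-CLIM change called 0 probe sets on each array, so that all 100 pairs of splits gave as many, with at most 2 on the A array and 1 on the B array.

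The first pattern is the correlation of both proteins' fold changes: after a trend on mean signal was subtracted from each array's difference the A array correlation was 0.255 against 0.278 before, which argues against an intensity-dependent difference between arrays as its whole source. The 3' to 5' ratio of ACTB rose in 3 of 6 pairs and that of GAPDH in 2, which argues against RNA integrity. Chance was not excluded: 11 of 100 pairs of splits gave an absolute correlation as large on the A array (highest other 0.411) and 5 of 100 on the B array (real 0.112, highest other 0.166). Among the 16 pairs of splits that part every pair of arrays the real value was the largest, with a highest other of 0.191 on the A array and 0.0739 on the B array, and 16 are too few for a share under 0.05. Doxycycline withdrawal cannot be told apart from a response shared by both proteins, because 0 arrays here hold cells without a transgene.

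The second pattern is the lower mitochondrial ribosome list in DN-CLIM high. After the same trend was subtracted the list's median log2 fold change was -0.13, against -0.18 before, and lay below the 2.5th percentile (-0.07) of 10000 random lists matched on mean signal, which argues against an intensity-dependent difference as its whole source. The random lists describe these arrays and leave out the correlation between the list's genes. The camera call was lost with an estimated correlation of 0.0858 (adjusted p = 0.265). It was also lost with the block (adjusted p = 0.260), where the estimate was -0.000339, so correlation between the genes does not by itself account for the loss. As many lists as the real 5 came from 6 of 10 splits of the DN-CLIM arrays, but from none of the 3 others that part every pair (highest other 4), and neither number of splits allows a share under 0.05. A response to DN-CLIM and one to doxycycline withdrawal stay open.

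The third pattern is the lower interferon list with both proteins. Its shift was negative in 6 of 6 cell lines, which argues against a single cell line as its source, although leaving out single arrays ended the call in both tables. In the DN-CLIM table the median was -0.06 without low replicate 3 and -0.02 without high replicate 1. Each of these fits kept the other array of the pair, so these medians also hold differences between cell lines. Within DN-CLIM cell lines 1, 2 and 3 the list's shift was -0.37, -0.16 and -0.84. With quantile normalization the DN-CLIM median was -0.43 against -0.39, which argues against an intensity-dependent difference and not against a dependence on single arrays. The genes of this list moved together (estimated correlation between genes 0.764 in the DN-CLIM table and 0.389 on the A array), but less with the replicate block (0.438 and -0.0222), and a difference between cultures in interferon tone, a response to both proteins and one to doxycycline withdrawal stay open as untested.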

How the results depend on the processing

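The combinations with the replicate block and the values with a pair left out were chosen only after the results had been seen. The values as deposited gave the same counts as the rescaled ones. Without the block, 0 probe sets were called in each of the 3 tables under every alternative, with limma and any array left out. The replicate block changed the count of calls only on the A array (14) and the count of lists only on the B array (2), and besides the list members given with their lists it changed no other call. Where a cause is not named below, the cause was not tested.

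The 14 block calls of the A array became 4 with quantile normalization, 0 with no filter, 56 with the upper 40% and 0 without the intensity trend. Leaving out each pair gave 0 to 244 on the A array, 0 to 13 on the B array and 0 to 11 for DN-CLIM. For the LMO4 change minus the DN-CLIM change on the B array, leaving out an array gave 0 to 1 calls.

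The 2 lists called on the A array became 1 with the upper 40% and 0 with an estimated correlation, and with the block 1 and 0. The B array count of 0 became 2 with the upper 40%, and its 2 with the block became 1 with a pseudocount of 64, 1 with no filter, 1 with the upper 40%, 0 without the trend and 0 with an estimated correlation. The 5 lists of the DN-CLIM table became 0 with an estimated correlation, with and without the block (0), and 3 with the mean over a gene's probe sets. Leaving out an array gave 0 to 3, 0 to 1 and 2 to 6 lists on the A array, the B array and for DN-CLIM, and leaving out a pair with the block 2 to 6, 0 to 2 and 4 to 5.

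The correlation of both proteins' fold changes was 0.135 on the A array and 0.0507 on the B array with no filter, where dim probe sets enter, and 0.227 on the B array with the upper 40%. Leaving out an array or a pair gave 0.106 to 0.316 and 0.0586 to 0.137.

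Named probe sets kept their sign and their side of the threshold in 2818 recomputed values, passed only in the new setting in 13, all with the replicate block, and turned sign in 26, all with an array left out and none of them past the threshold. Log2 fold changes of the 21 probe sets concerned ranged as follows with each array left out. For LMO4 on the A array LDB1 35160_at -0.061 to 0.34, HDAC2 201833_at -0.24 to 0.22, ITGAM 205785_at -0.012 to 0.44, CD3E 205456_at -0.11 to 0.34, CAV1 212097_at -0.046 to 1.28, LDB1 203451_at -0.25 to 0.13. For LMO4 on the B array LDB2 242360_at -0.047 to 0.31, CDT1 228868_x_at -0.24 to 0.020, HSPB8 233057_at -0.53 to 0.035, SSBP3 222482_at -0.010 to 0.19, IRS1 238933_at -0.14 to 0.44, ATF5 230938_x_at -0.13 to 0.85, HDAC2 242141_at -0.34 to 0.031, UHRF1 225655_at -0.051 to 0.35, AK4 225342_at -0.23 to 0.085, MDM2 225160_x_at -0.24 to 0.0027. For DN-CLIM HDAC2 201833_at -0.23 to 0.078, LDB1 35160_at -0.24 to 0.13, LDB2 242360_at -0.0086 to 0.49, COL1A2 202403_s_at -0.056 to 0.79, LMO4 209205_s_at -0.018 to 0.21. Of the 30 probe sets that the rule named by their values 0 moved by over 1.5 times with an array left out, and of the 177 other results 130 did. The rule picks separated arrays, large changes and small p, which favours such stability. This contrast is therefore no evidence that the named changes are robust. Lists kept the direction of the camera test and their side of the threshold in 532 recomputed values, lost the call in 27, gained it in 19 and turned direction in 43, all of them lists not called. Medians follow. With quantile normalization these were luminal epithelial markers (LMO4, A array) 0.0047 and luminal epithelial markers (DN-CLIM) -0.0075. With no filter these were basal and mesenchymal markers (LMO4, A array) 0.051, glycolysis and hypoxia (LMO4, B array) -0.046, luminal epithelial markers (LMO4, B array) -0.083 and basal and mesenchymal markers (DN-CLIM) 0.10. With the upper 40% of probe sets these were apoptosis regulators (LMO4, A array) -0.010 and apoptosis regulators (LMO4, B array) -0.026. With the replicate block it was estrogen response (LMO4, B array) -0.17. With the mean over a gene's probe sets these were apoptosis regulators (LMO4, B array) -0.026 and glycolysis and hypoxia (DN-CLIM) -0.0010. With no intensity trend it was glycolysis and hypoxia (DN-CLIM) -0.020. With each array left out these medians ranged as follows. For LMO4 on the A array luminal epithelial markers -0.068 to 0.086, basal and mesenchymal markers -0.043 to 0.17, cholesterol synthesis -0.16 to 0.062, integrated stress response -0.018 to 0.13, cell cycle 0.026 to 0.12. For LMO4 on the B array glycolysis and hypoxia -0.13 to 0.085, luminal epithelial markers -0.058 to 0.17, apoptosis regulators -0.091 to 0.052, estrogen response -0.18 to 0.035, LIM complex -0.029 to 0.15, integrated stress response -0.081 to 0.13. For DN-CLIM luminal epithelial markers -0.066 to 0.031, basal and mesenchymal markers -0.061 to 0.18, glycolysis and hypoxia -0.17 to 0.13, BMP and TGF-beta signalling -0.049 to 0.14, cell cycle -0.097 to 0.14, estrogen response -0.058 to 0.24, integrated stress response 0.0012 to 0.17. Of the turned values 1 passed the threshold, glycolysis and hypoxia without DN-CLIM high replicate 1 (-0.17).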

Other observations

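The metallothionein list, the genes of the next paragraph and the comparison of A and B arrays were chosen only after the array values had been seen. Metallothioneins bind zinc and copper and were not among the fixed lists. In LMO4 high all 10 of their probe sets tested on the A array had a log2 fold change above 0, with a median over 7 genes of 0.46 and means of 0.43, 0.67 and 0.55 in cell lines 1, 2 and 3. A candidate explanation is a change shared with DN-CLIM high, which would follow if it came from doxycycline withdrawal or the cofactor complex. The median over 7 genes in the DN-CLIM table was 0.28 and 6 of them were higher. The DN-CLIM cell lines differed, with means of 0.98, -0.08 and 0.04 in cell lines 1, 2 and 3, medians of 0.68, -0.06 and 0.33 (LMO4 0.42, 0.71 and 0.62) and 7, 1 and 4 of 7 genes higher, so that a shared change stays open. Their probes match several members of the family, so that these probe sets are not independent.

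Some further genes had the same sign for both proteins, and they were picked by their values, without a test of any group of them. IGFBP2 had log2 fold changes of 0.46 with LMO4 and 0.86 with DN-CLIM, and GLUL, which makes glutamine, 0.48 and 0.72. On the lower side were the tight junction protein OCLN (-0.42 and -0.45), the engulfment adaptor GULP1 (204237_at, -0.73 and -0.77), PSG6 (-0.61 and -0.54) and, on the B array, the STAT1-related ubiquitin ligase DTX3L (-0.51 and -0.41). PSG6 and PSG9 are near-identical members of 1 family and rest on x_at probe sets. Each of these genes had the same sign in 3 of 3 cell lines of each protein, and none passed the threshold in either table. They were picked for the same sign and an unadjusted p under 0.01 with the replicate block in both tables. This favours such agreement between cell lines, which is therefore no added evidence.

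The A and B arrays share 100 probe sets, and their LMO4 fold changes on both arrays had a correlation across probe sets of 0.447, with a median absolute difference of 0.08 on the log2 scale. Of 6 A arrays, 4 correlated best with the B array of their own title. Correlations ran from -0.021 to 0.517 for arrays of the same title and from -0.465 to 0.285 for arrays of different titles.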
